A study of Mus musculus with 9 samples.

How the data were processed

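The data are 9 Affymetrix mouse expression arrays of the cell line m-ICcl2, with 3 arrays for each of 3 conditions. Per the labels, total RNA was isolated with TRIzol, checked on a Bioanalyzer and labelled with biotin by the array maker's standard protocol. The deposited values are probe-set intensity on a linear scale, 1 value per probe set and array, made with GCRMA per the submitters' processing notes; its version is not given in the sources used here. GCRMA subtracts a background modelled on probe sequence and normalizes between arrays, so low values crowd near a floor, where differences carry no order. The single lowest value of each array was 2.22 to 2.25 on the linear scale. The array medians over all probe sets but controls were log2 3.00 to 3.04.

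All further steps were made here in R 4.3.3 with limma 3.58.1. Values were turned into log2 without a pseudocount. Of 45101 probe sets, 64 were controls, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 had no listed gene; probe sets of the last kinds were left out of the gene tests. Each gene was represented by its probe set with the highest mean over the 9 arrays, which gave 18193 genes. For Nfkbiz, Nfkbia, Tnfaip3, Tlr4, Arhgap24, Top2a, Mvk, Ccn1 and Ddit3 another probe set at or above the level minimum differed in its change by over 1.5-fold in at least 1 comparison. Genes at log2 4 or more on at least 3 of 9 arrays were tested, 9431 genes or 51.8%. A gene below log2 4 on all arrays of 2 conditions thus entered only by being higher in the remaining condition. Where all 3 arrays of the lower group lay below log2 4, the fold is given as a lower bound, the higher group's mean against log2 4, and for other low genes the number of such arrays is given.

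Groups came from the treatment labels. The main model was limma's lmFit with a mean per condition over all 9 arrays, leaving 6 residual degrees of freedom, followed by eBayes without trend, and two-sided moderated tests with Benjamini-Hochberg adjustment within each of 3 comparisons at a threshold of 0.05. Lists of genes, 27 with 580 genes, were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives but those named at the end. The 23 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. Of the listed genes, 44 had no probe set of their own and are not analysed here. A further 230 were on the array but below the level minimum and were not tested. Measured members of a list are those that passed this minimum. The rule named the 8 largest rises and 8 largest falls, as measured and so with values near the floor included, among calls with fully separated arrays, leaving out clone-like symbols, at most 4 measured members of each list by size of change, and the TLR4 index genes in every comparison.

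Same-numbered arrays of different conditions deviated together. The labels give every condition replicates 1, 2 and 3 without saying what a number shares, and the correlation across genes of deviations from the condition means lay between 0.157 and 0.844 for every same-numbered pair (0.737 to 0.844 for replicate 1). Differently numbered arrays of replicates 2 and 3 correlated at 0.214 to 0.731, as much as same-numbered ones, and arrays of replicate 1 with those of replicates 2 and 3 at -0.743 to -0.375, so that only replicate 1 stood apart. The rule set beforehand for pairing, a correlation above 0.1 in every same-numbered pair, was met. It cannot tell pairing from a replicate 1 that stands apart, since arrays of replicates 2 and 3 correlated as much across numbers. Whether numbers 2 and 3 pair the samples stays open. Values with the replicate number as a block are printed beside the counts of genes and for most list counts that the block changed, but not for every named gene. No slide or scan date was used here.

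The steps were tested on simulated data with each gene's real mean and residual spread but no replicate structure. The rates below therefore hold for such data and need not hold for the real arrays. At the comparison of 6 h LPS with unstimulated cells, over 9431 genes, 32 of 100 genes changed 2-fold and 90 of 100 changed 4-fold were recovered, with 3.17% false calls. For tolerant against unstimulated these values were 41, 86 and 6.62%, and for tolerant against 6 h they were 35, 83 and 5.6%. Alternatives covered the filter, the rule for several probe sets, further normalization, a floor, the eBayes settings, separate fits, the replicate block, a fold threshold within the test and each array left out in turn. Those added after seeing the data were the fit on replicates 2 and 3 only and a block of replicate 1 against the others.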

Results

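Genome-wide transcript levels were measured on 9 Affymetrix arrays in m-ICcl2 cells, a mouse small intestinal epithelial line that carries the SV40 large T antigen. Each of 3 conditions had 3 arrays, labelled as biological replicates. Cells were left unstimulated, exposed for 6 h to lipopolysaccharide (LPS, the endotoxin of Gram-negative bacteria) at 100 ng/mL, or exposed for 6 h and then kept for 90 h in medium free of LPS. The last condition, sampled 96 h after LPS was first added, is called tolerant in the series design and here. The unstimulated arrays carry no culture time in the labels, so time in culture and earlier LPS exposure cannot be told apart in the tolerant cells. The medians of the 9 arrays over the tested genes lay between 7.62 and 7.84 on the log2 scale, and 59.1% to 61.0% of probe sets lay below log2 4. Array data give no read depth, and the number of arrays limits the precision.

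The tolerant arrays stood apart from the other 6 on the first principal component, which held 44.3% of the variance. The next component, with 30.9%, separated replicate 1 from replicates 2 and 3 in all 3 conditions. In replicate 1 the log2 difference between the 3' and 5' control probe sets of beta-actin was 0.72 in unstimulated, 0.40 in 6 h LPS and 0.66 in tolerant cells, against 1.02 to 1.38 on the other 6 arrays. For Gapdh this difference was -0.12, -0.06 and -0.20 in replicate 1 and -0.24 to -0.16 on the other 6 arrays, so these ranges overlapped. The 5' probe set for 18S ribosomal RNA read 7.27, 8.08 and 10.24 on the replicate 1 arrays and 3.38 to 5.76 on the others (log2). On the third component, with 16.2%, 6 h LPS replicates 1 and 2 lay at -0.71 and -0.47, and 6 h LPS replicate 3 at 0.01. Counts of genes below are therefore also given with the replicate number as a block and from replicates 2 and 3 only.

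**Figure D1:**
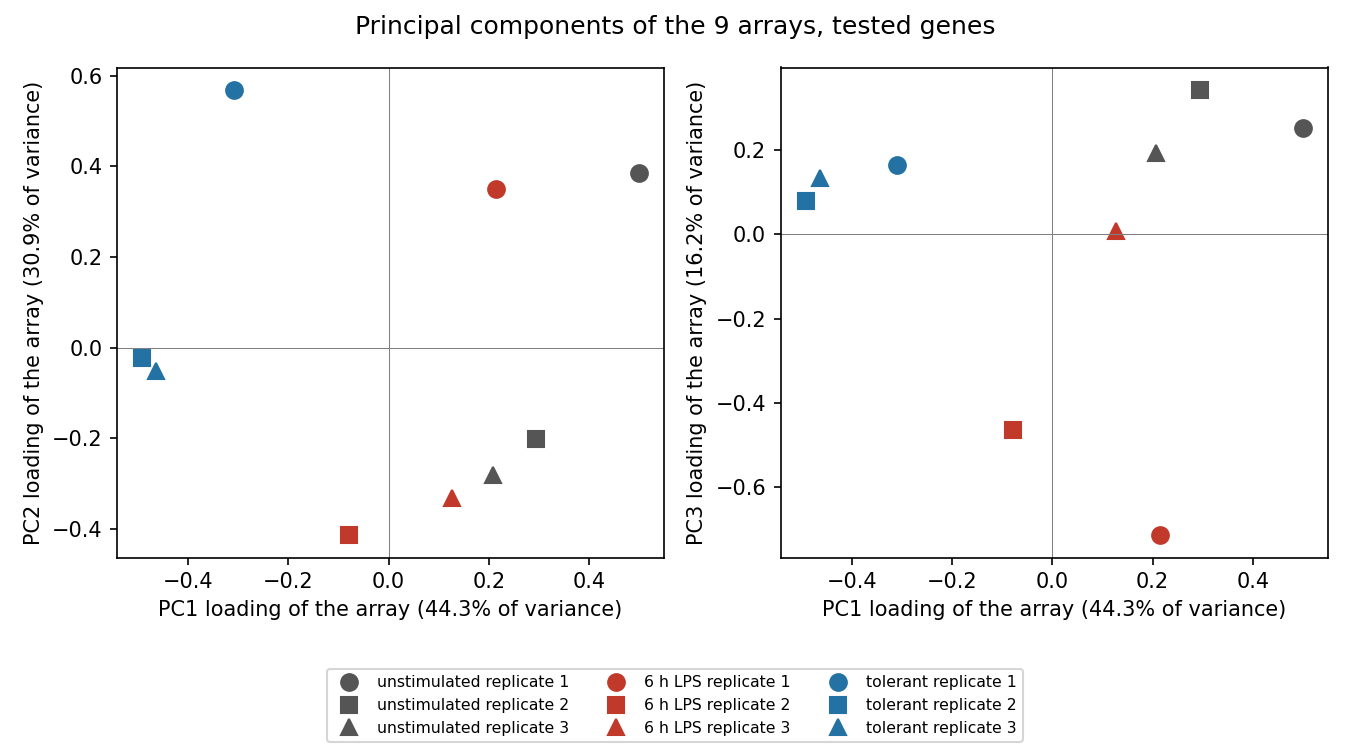
Loadings of the 9 arrays on principal components 1 and 2 (left) and 1 and 3 (right), each axis labelled with its percent of variance; colours mark conditions and symbols mark replicates. All tolerant arrays lie below -0.30 on component 1, all replicate 1 arrays lie above 0.34 on component 2, and 6 h LPS replicates 1 and 2 lie at -0.71 and -0.47 on component 3.

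The first comparison asked what 6 h of LPS changed. Transcripts of 4 chemokines, secreted attractants of neutrophils and monocytes, rose. Cxcl5 rose 67.7-fold, from a log2 level of 5.87 ± 0.28 to 11.95 ± 0.11 (SD, n = 3; adjusted p = 3.99e-05), and Cxcl1 rose 17.3-fold, from 7.45 ± 0.14 to 11.57 ± 0.20 (adjusted p = 2.24e-05). Cxcl2 rose at least 11.9-fold and Ccl2 at least 12.7-fold, since both lay below log2 4 on all 3 unstimulated arrays. The remaining calls were Neurl3, which rose at least 2.33-fold, and Nfkbiz, the gene of an atypical inhibitor-of-kappa-B protein, which rose 5.0-fold (adjusted p = 0.00621), with changes of 0.40 to 2.60 log2 over its 3 probe sets. These 6 genes were all that limma called among 9431 tested, and each was higher in all 3 same-numbered pairs of arrays. None was called lower, although 2163 genes had an unadjusted p below the threshold in either direction.

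**Figure D2:**
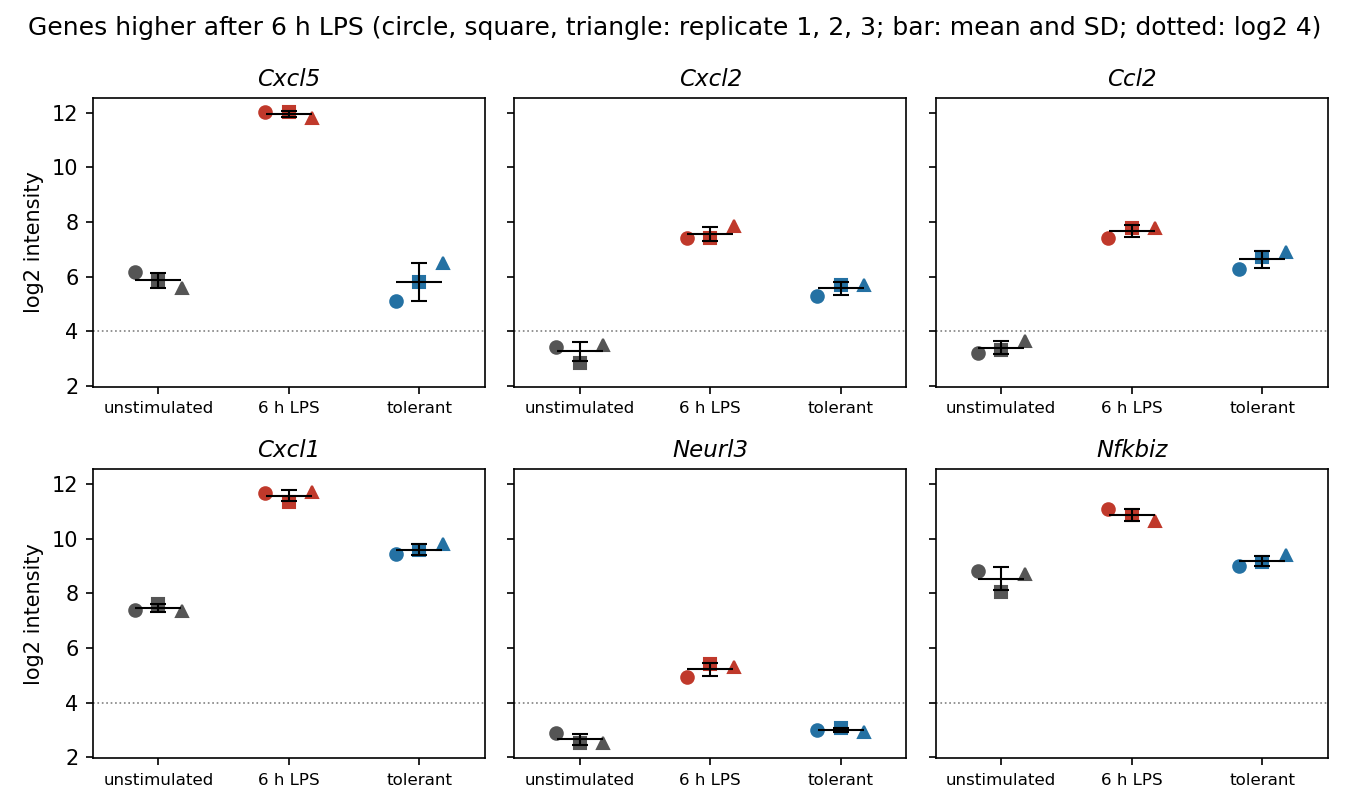
Log2 intensity of the 6 genes called higher after 6 h of LPS, one point per array (circle, square and triangle for replicates 1, 2 and 3), with the mean and SD of each condition; the dotted line marks log2 4. Cxcl5 returned from a mean of 11.95 at 6 h to 5.81 in tolerant cells, while Ccl2 stayed at 6.64, above its 3 unstimulated arrays, which all lie below log2 4.

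The count at 6 h depended on the replicate block and on 6 h LPS replicate 3. With the replicate block, 1092 genes were higher and 1175 lower, 255 of them by at least 2-fold (237 up and 18 down), and the 6 genes remained among them. From replicates 2 and 3 alone, 8 genes were higher and 0 lower, and without 6 h LPS replicate 3, 503 were higher and 193 lower. The median log2 change over all tested genes was -0.11, so small falls at 6 h are to be read relative to that shift. Across genes, which are not independent replicates, the changes in replicate 1 correlated with those in replicates 2 and 3 at r = 0.72.

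Among the lists fixed beforehand, 4 of 7 measured chemokines rose at 6 h over all genes tested, and 4 when adjusted over the list alone (camera adjusted p = 8.03e-08, and adjusted p = 0.0601 with an estimated correlation). Of 14 measured genes of the NF-kappa-B module, 1 rose, Nfkbiz, and 5 were higher when adjusted over the list alone and 6 with the replicate block (camera adjusted p = 0.0224, and adjusted p = 0.343 with an estimated correlation). Birc3 was 2.41-fold and Nfkbia 1.83-fold higher without passing the test (adjusted p = 0.115 and 0.128), and both passed with the replicate block (adjusted p = 0.0297 and 0.0272). The 5 probe sets of Nfkbia were higher by 0.87 to 1.76 log2, the one used here being the lowest. Of 5 measured acute-phase and antimicrobial genes none passed, and 3 were higher both when adjusted over the list alone and with the block (camera adjusted p = 0.00119, and adjusted p = 0.0601 with an estimated correlation). Lcn2, the siderophore-binding lipocalin, had a log2 level of 12.79 ± 0.39 against 11.43 ± 0.54 (SD, n = 3; adjusted p = 0.115, or 0.0115 with the block). Of 18 measured apoptosis genes none passed, 7 were higher when adjusted over the list alone and 8 with the block (camera adjusted p = 0.00195, and adjusted p = 0.0601 with an estimated correlation). Of 25 measured oxidative phosphorylation genes none passed, also when adjusted over the list alone, and 3 were lower with the block, with a median of -0.22 (camera adjusted p = 0.0463 downward, 0.0895 with the block, and adjusted p = 0.361 with an estimated correlation).

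The TLR4 index genes formed the remaining list with a camera call at 6 h (adjusted p = 8.49e-06, and adjusted p = 0.0601 with an estimated correlation). Cxcl2 was the single one of 8 measured members to rise over all genes tested, and 4 were higher both when adjusted over the list alone and with the block. Tnfaip3, which encodes the deubiquitinase A20, was 3.69-fold higher (adjusted p = 0.0625) and Tlr4 2.31-fold higher (adjusted p = 0.115), and both passed with the block (adjusted p = 0.0243 and 0.0319). The other probe set of Tnfaip3 was higher by 0.89 log2. Cd14 (adjusted p = 0.222), Ly96 (0.432), Irak1 (0.783) and Traf6 (0.217) did not pass. Tnf and Il6 stayed at the low end on all 9 arrays, with highest log2 values of 2.45 for Tnf and 2.24 for Il6, and were not tested.

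The second comparison set tolerant against unstimulated cells. Cd68, a lysosomal glycoprotein gene, rose 17.8-fold from a log2 level of 5.52 ± 0.13 to 9.67 ± 0.06 (SD, n = 3; adjusted p = 5.83e-06), and Uox, the urate oxidase gene, rose 13.9-fold. The cytokine gene Il24 rose 23.4-fold with 2 of 3 unstimulated arrays below log2 4, and the matrix metalloproteinase gene Mmp7 23.3-fold with 1 of 3 below. Bounds were at least 16.5-fold for Siglecg, 14.3-fold for S100g, the gene of an intestinal calcium-binding protein, 11.6-fold for Slc5a10 and 9.36-fold for Nlrp10, an NLR family gene (adjusted p = 1.18e-06). Among the falls, Kif12 fell 7.91-fold and Arhgap24 7.62-fold (-1.84 log2 on its other probe set). Ddc, the aromatic amino acid decarboxylase gene, fell 11.5-fold with 1 of 3 tolerant arrays below log2 4, and Cbr2 9.11-fold with 2 of 3 below. Sgk2 fell at least 6.12-fold, Tspyl4 at least 5.63-fold, Pcolce2 at least 3.19-fold and Dmtn at least 2.8-fold. Genes with such bounds have no order of size among these. In all, limma called 1318 genes higher and 1152 lower, 26.2% of those tested, and 1394 changed by at least 2-fold (818 up and 576 down).

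With the replicate block, 2142 genes were higher and 2444 lower in tolerant than in unstimulated cells, and from replicates 2 and 3 alone 1749 and 1859. The total was 1515 without unstimulated replicate 2, 1400 without tolerant replicate 2 and 1543 without tolerant replicate 3.

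Immediate-early genes, the transcription factors induced first by many stimuli, were the tested list with the largest share of raised members in tolerant cells. Of 18 measured, 12 rose and 1 fell over all genes tested, and 13 and 1 both when adjusted over the list alone and with the block (camera adjusted p = 0.000168, and adjusted p = 0.192 with an estimated correlation). Fos rose 10.4-fold and Egr1 5.48-fold, and Klf2 fell at least 2.41-fold. Egr2 of this list lay below log2 4 on every unstimulated and 6 h array and passed the filter only through its tolerant arrays. Its presence favours a rise of the list in both comparisons with tolerant cells. Of 7 measured chemokines 4 rose, both over all genes tested and adjusted over the list alone (camera adjusted p = 0.00415, and adjusted p = 0.204 with an estimated correlation): Ccl2 by at least 6.21-fold, Cxcl2 by at least 2.98-fold, Cxcl1 by 4.45-fold and Cxcl10 by at least 2.65-fold. Negative regulators of TLR signalling rose in 7 of 15 measured genes, 8 when adjusted over the list alone and 9 with the block (camera adjusted p = 0.00212, and adjusted p = 0.0928 with an estimated correlation). Among them were Tnfaip3 (5.07-fold, with a rise of 1.22 log2 on its other probe set), Cyld (2.32-fold), Atf3 (2.23-fold) and Zfp36 (2.23-fold).

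Of 8 measured index genes 4 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.204 with an estimated correlation). Besides Cxcl2 and Tnfaip3 these were Tlr4, from a log2 level of 5.50 ± 0.25 to 7.63 ± 0.32 (SD, n = 3; adjusted p = 0.000939), and Nfkbia, which rose 1.8-fold (adjusted p = 0.0456). Cd14 (adjusted p = 0.192), Ly96 (0.972), Irak1 (0.782) and Traf6 (0.559) did not pass. The adaptor gene Myd88 fell 2.35-fold (adjusted p = 0.0108). Of the TLR signalling list, 1 of 16 measured genes rose and 1 fell, also when adjusted over the list alone, and 1 and 2 with the block, with no camera call (adjusted p = 0.81). In the NF-kappa-B module 3 of 14 rose, 2 when adjusted over the list alone (camera adjusted p = 0.0192, and adjusted p = 0.205 with an estimated correlation), including Birc3 (3.82-fold) and Birc2 (3.36-fold), and 8 rose and 1 fell with the block.

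Cell-cycle genes were higher as well: of 33 measured, 13 rose and 1 fell, or 14 and 1 when adjusted over the list alone and 17 and 3 with the block (camera adjusted p = 0.0036, and adjusted p = 0.0928 with an estimated correlation). Examples were Bub1 (5.29-fold), Mki67 (4.62-fold) and Top2a (3.74-fold). Epithelial junction genes rose in 8 of 16 measured, 9 when adjusted over the list alone, and with the block 10 rose and 1 fell (camera adjusted p = 0.00212, and adjusted p = 0.0928 with an estimated correlation). The claudin gene Cldn4 was up by 3.33 log2, Epcam at least 3.11-fold and Tjp1 2.81-fold. Of 5 measured adhesion and matrix-remodelling genes 3 rose, and 3 when adjusted over the list alone (camera adjusted p = 0.00415, and adjusted p = 0.178 with an estimated correlation), among them Plat (5.77-fold). Apoptosis genes rose in 7 of 18 measured and fell in 1, or 7 and 2 when adjusted over the list alone and 8 and 4 with the block (camera adjusted p = 0.0189, and adjusted p = 0.157 with an estimated correlation). Pmaip1 rose 4.85-fold and Casp4 at least 3.42-fold. The cytokine list had 2 of 6 measured genes higher, 2 when adjusted over the list alone and 4 with the block (camera adjusted p = 0.0341, and adjusted p = 0.204 with an estimated correlation), Il33 by at least 1.75-fold and Tgfb2 by at least 1.28-fold. Both lay below log2 4 on every unstimulated and 6 h array and passed the filter only through their tolerant arrays. The share raised and the list test therefore favour a rise. The same limit holds for Epcam in the junction list, in both comparisons with tolerant cells. Glycolysis and hypoxia genes rose in 5 of 17 measured and fell in 1, or 7 and 1 when adjusted over the list alone and 7 and 2 with the block, with Hk2 up 3.6-fold. They passed camera only with the block (adjusted p = 0.0597 without it and 0.0283 with it, and adjusted p = 0.377 with the block and an estimated correlation).

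Lower in tolerant cells were genes of the oxidative-stress (NRF2) response, of which 4 of 15 measured fell, 4 when adjusted over the list alone and 8 with the block (camera adjusted p = 0.035, and adjusted p = 0.204 with an estimated correlation). The heme oxygenase gene Hmox1 fell 4.9-fold, Gsta4 2.35-fold and the metallothionein gene Mt1 2.01-fold. Of 25 measured oxidative phosphorylation genes 1 fell over all genes tested, Atp5o, and 0 when adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.204 with an estimated correlation), and 9 fell with the block. Enterocyte genes moved both ways, with 2 of 10 measured higher and 2 lower, also when adjusted over the list alone, and 4 and 2 with the block (camera adjusted p = 0.959). Cdh17 rose 4.13-fold and Krt20 1.69-fold, whereas Hnf4a fell 3.49-fold and Mep1a 2.56-fold. Of 20 listed macrophage and leukocyte genes 3 passed the level minimum, which was too few for a list test. Cd68 rose while Csf1r fell 3.85-fold and Spi1 at least 1.94-fold.

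**Figure D3:**
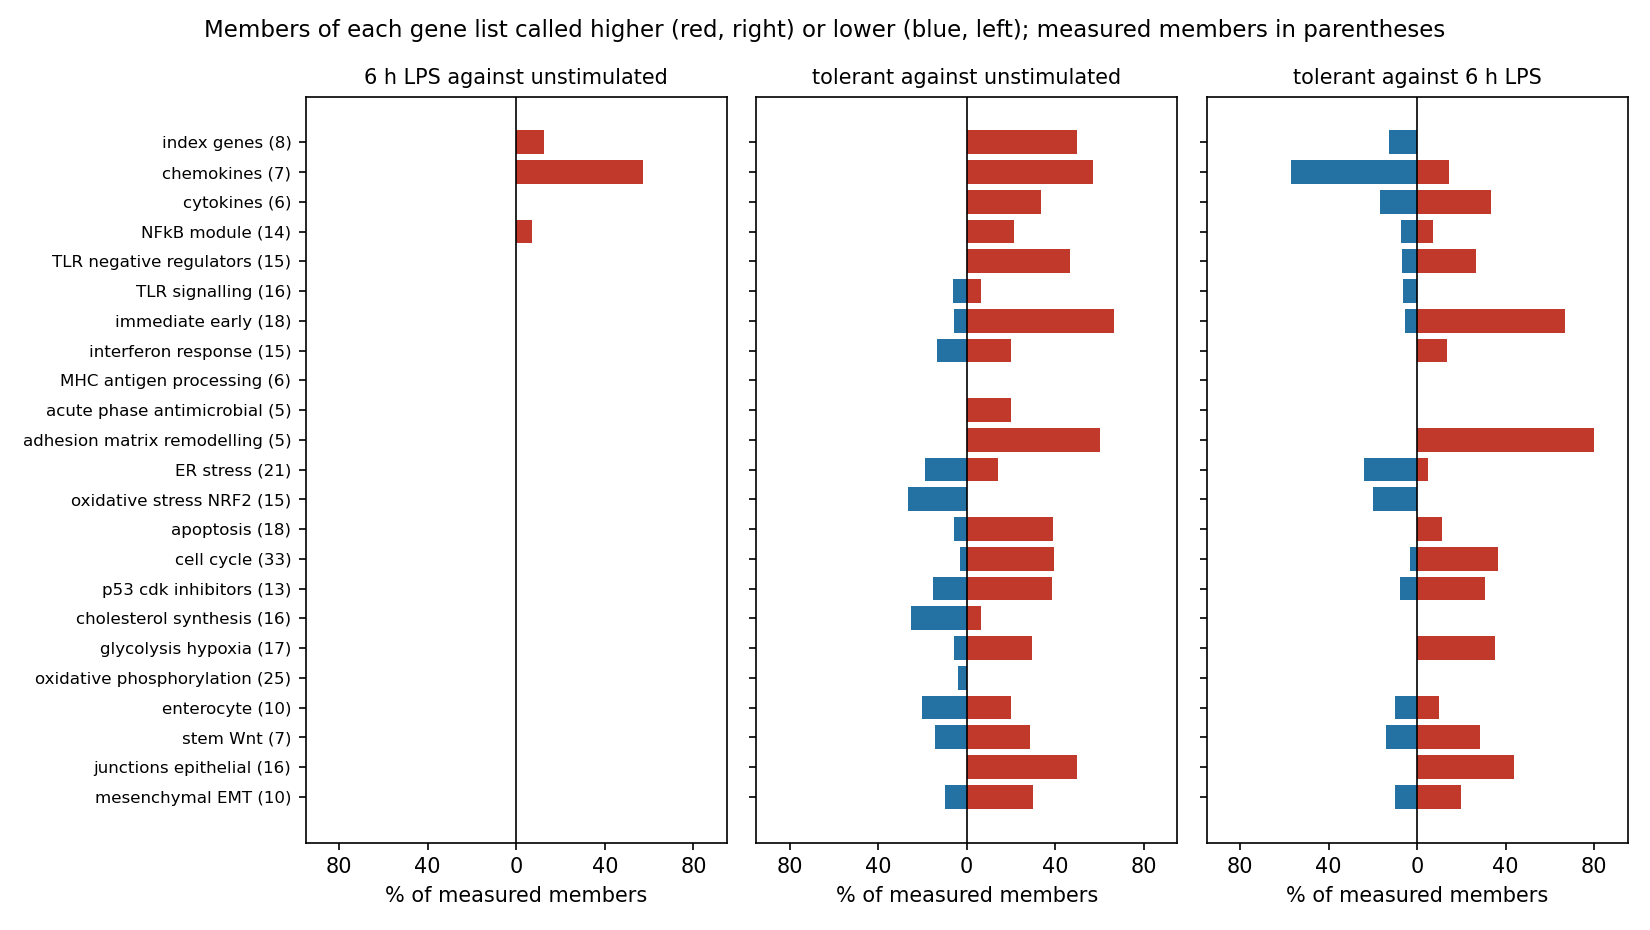
Percent of the measured members of each list called higher (red, to the right) or lower (blue, to the left) in each comparison, adjusted over all genes tested; the number of measured members stands in parentheses. Chemokines were higher in 4 of 7 measured members at 6 h and lower in 4 of 7 between 6 h and the tolerant state, while immediate-early genes were higher in 12 of 18 members in both comparisons with tolerant cells.

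The third comparison set tolerant cells against cells at 6 h of LPS. Cxcl5 fell 70.6-fold, from a log2 level of 11.95 ± 0.11 to 5.81 ± 0.70 (SD, n = 3; adjusted p = 2.79e-05). The long noncoding RNA Neat1 fell 9.28-fold, Ttc30b at least 4.85-fold, Sgk2 at least 4.5-fold, Tspyl4 at least 4.76-fold and Arhgap24 7.11-fold (-1.54 log2 on its other probe set). S100g rose at least 14.3-fold, Nlrp10 at least 9.36-fold, Siglecg at least 16.5-fold, Cd68 23.7-fold and Il24 21.3-fold, the last with 1 of 3 arrays at 6 h below log2 4. Sprr1a, a cornified-envelope gene, rose 16.8-fold and Cldn4 14.5-fold. In all, limma called 670 genes higher and 568 lower, 13.1% of those tested, and 728 of them changed by at least 2-fold (419 up and 309 down).

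With the replicate block, 1508 genes were higher and 1477 lower in tolerant cells than at 6 h, and from replicates 2 and 3 alone 1055 and 1071. The total was 766 without tolerant replicate 1, 677 without tolerant replicate 2 and 704 without tolerant replicate 3.

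Of 7 measured chemokines 4 fell from 6 h to the tolerant state and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00997 downward, 0.0478 with the block, 0.119 from replicates 2 and 3, and adjusted p = 0.245 with an estimated correlation). Cxcl2 fell 3.99-fold and Cxcl1 3.9-fold, whereas Cxcl10 rose 2.36-fold. Nfkbiz fell 3.2-fold and Tlr2 at least 2.56-fold. Of the index genes, Cxcl2 was the single one of 8 that passed, with 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.387). Tlr4 was 1.9-fold higher (adjusted p = 0.0523, or 0.0277 with the block), with changes of 0.43 to 1.61 log2 over its 3 probe sets. Traf6 was at least 1.07-fold lower, with its tolerant arrays all below log2 4 (adjusted p = 0.0731, or 0.0235 with the block). Nfkbia (adjusted p = 0.97), Tnfaip3 (0.313), Cd14 (0.886), Ly96 (0.409) and Irak1 (0.613) did not pass. The probe sets of Nfkbia differed by -0.93 to -0.03 log2 in this comparison.

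Cell-cycle genes rose in 12 of 33 measured and fell in 1, or 16 and 1 when adjusted over the list alone and 18 and 1 with the block. This was the single list whose call held with an estimated correlation and no block (camera adjusted p = 2.99e-05, and adjusted p = 0.0418 with an estimated correlation). With the block and an estimated correlation that call was lost (adjusted p = 0.309). Cenpa rose 4.74-fold, Mki67 3.06-fold and Bub1b 3.04-fold. Immediate-early genes rose in 12 of 18 measured and fell in 1, or 13 and 1 when adjusted over the list alone and 14 and 1 with the block (camera adjusted p = 3.65e-07, and adjusted p = 0.103 with an estimated correlation), with Fos up 11.5-fold and Egr1 6.12-fold. Epithelial junction genes rose in 7 of 16 measured, 9 when adjusted over the list alone, and with the block 9 rose and 1 fell (camera adjusted p = 0.000271, and adjusted p = 0.0505 with an estimated correlation). Those raised included Ocln (2.06-fold) and Krt18 (2.07-fold). Glycolysis and hypoxia genes rose in 6 of 17 measured, 7 when adjusted over the list alone and 9 with the block (camera adjusted p = 0.00595, and adjusted p = 0.103 with an estimated correlation). The glucose transporter gene Slc2a1 rose 5.1-fold, Egln3 3.3-fold and Hk2 2.79-fold. Adhesion and matrix-remodelling genes rose in 4 of 5 measured, and 4 when adjusted over the list alone (camera adjusted p = 0.00151, and adjusted p = 0.103 with an estimated correlation). Negative regulators of TLR signalling rose in 4 of 15 and fell in 1, or 5 and 1 when adjusted over the list alone and 6 and 1 with the block (camera adjusted p = 0.00595, and adjusted p = 0.103 with an estimated correlation). Dusp1 rose 2.72-fold, and Zc3h12a fell at least 2.03-fold. The oxidative-stress and ER-stress lists passed camera with the block (adjusted p = 0.0188 and 0.0315, and adjusted p = 0.341 and 0.309 with an estimated correlation) and not over all 9 arrays without it (0.0653 for both). From replicates 2 and 3 alone the oxidative-stress list passed (adjusted p = 0.0237) and the ER-stress list did not (0.0926).

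The 3 conditions were then set side by side for the genes raised at 6 h. Of the 6 raised by at least 2-fold, 3 were still raised in tolerant cells: Ccl2, Cxcl1 and Cxcl2. With the replicate block Nfkbiz also passed as still raised (0.64 log2, adjusted p = 0.0329, against 0.0738 without the block). Cxcl1 kept 52.3% of its log2 rise, and no share is given for Ccl2 and Cxcl2, whose unstimulated arrays all lay below log2 4. All 6 were lower in tolerant cells than at 6 h, a fall to which selection on the 6 h arrays can contribute by an amount that was not measured. Cxcl5 differed from unstimulated cells by -0.06 on the log2 scale (adjusted p = 0.912). Simulated tolerant arrays set equal to the unstimulated ones gave 0 still raised in all 100 draws, and simulated arrays set equal to 6 h gave 0 lower in all 100. Both simulations hold no replicate structure. Of 100 drawn splits of the real arrays 5 gave at least 3 still raised, and 3 of 100 did among splits within replicate numbers, which were added later. With the replicate block, 237 genes were raised by at least 2-fold at 6 h, of which 190 were still raised and 29 were lower than at 6 h, 4 of them both. From replicates 2 and 3 alone, 7 were still raised and 5 lower, and without 6 h LPS replicate 3, 297 and 53.

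The log2 changes at 6 h and in tolerant cells, both against the same unstimulated arrays, correlated across genes at r = 0.558, where unchanged groups sharing those arrays gave 0.4996 on average in 100 simulations. Their covariance was 0.208 against a simulated 0.0553, a difference of 0.153. The simulated correlation and covariance also hold no replicate structure. Under the block, 772 genes were raised in both comparisons and 669 lowered in both, where independent lists would share 248.0 and 304.5. No split of the 3 unstimulated arrays leaves 2 in each part, so the controls were not split, and part of the excess may come from the shared controls. Genes changed late were those called and changed by at least 2-fold against unstimulated cells, and called in the same direction against 6 h. The rule did not ask that a gene be unchanged at 6 h. With the replicate block, Neat1, Tfrc and Ppbp met it as lower in tolerant cells although raised by at least 2-fold at 6 h. Genes changed late numbered 692 (376 higher and 316 lower), 1094 with the replicate block and 920 from replicates 2 and 3, and 459 without tolerant replicate 2. Nlrp10, Il24, Cd68 and Cldn4 were among the higher and Sgk2, Kif12 and Arhgap24 among the lower.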

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

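The tests of beta-actin control probe sets, of the ratios of residual variance, of replicate 1's deviations, of the LPS-raised genes on 6 h LPS replicate 3, of leukocyte transcripts and of splits within replicate numbers were chosen only after the results they bear on were seen.

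Probe sets outside the gene tests, without a single named gene, also changed in both comparisons with tolerant cells. Of 1807 such probe sets at or above the level minimum, 229 changed by at least 2-fold in tolerant against unstimulated cells (170 higher and 59 lower), and 126 in tolerant cells against 6 h LPS (77 higher and 49 lower). At 6 h of LPS against unstimulated cells limma called 0 of them at that size, although 125 had an unadjusted p below the threshold with a change of at least 2-fold.

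The first pattern is the rise from 6 calls at 6 h without a replicate block to 2267 with it. The first bound written for a batch effect, a median ratio of residual variances with and without the block below 0.5, was missed at 0.515. That bound had no basis in the design. In a second test, written after this miss, 20 simulations without a batch gave ratios of 1.05 to 1.07, at least 0.539 above the observed one. That result follows from the correlation of same-numbered arrays and the rise in calls already seen, so it decides nothing. In this balanced design the block leaves each log2 change as it is (for example 2.32 for Nfkbiz in both fits), so the added calls come from a lower residual spread. What the numbers share, a batch included, stays open. A different LPS response of replicate 1 is not the whole cause, since its deviations in unstimulated cells, which saw no LPS, correlated with those in LPS-treated cells at 0.759 or more across genes. A difference in RNA quality or labelling of replicate 1 stays open: its highest beta-actin 3' minus 5' difference lay 0.301 log2 below the lowest of the other 6 arrays. The same difference for Gapdh did not separate replicate 1, since tolerant replicate 1 at -0.20 lay within the -0.24 to -0.16 of those 6 arrays.

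The next pattern is that 6 h LPS replicate 3 lay nearer to the unstimulated arrays than 6 h LPS replicates 1 and 2, and that 696 genes were called without it. An unstimulated sample with a wrong label is argued against by the median rise of 4.37 log2 in Cxcl5, Cxcl1, Cxcl2, Ccl2 and Nfkbiz on that array. These genes were called in a fit that included this array, which favours high values on it, so their choice was not independent of the test. A candidate explanation is more unspliced or nuclear RNA in 6 h LPS replicates 1 and 2, for which probe sets without a listed gene had to rise more than named ones there than in replicate 3 by over 0.1, and did by 0.226 and 0.200 log2. Malat1 and Neat1, nuclear RNAs chosen after their values were seen, were 1.03 and 2.55 log2 above the same-numbered unstimulated array in replicate 1 and 0.09 and 0.93 in replicate 3. In tolerant cells probe sets without a listed gene also lay above named ones (medians of 0.09 to 0.13 against -0.03 to 0.02 log2). Neat1 was 1.45 log2 below unstimulated cells there, so a rise of such probe sets need not mean more nuclear RNA. A weaker response of replicate 3 outside the chemokines was not tested and stays open.

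The last pattern is the rise of Cd68 and Siglecg, genes known from leukocytes, in tolerant cells of an epithelial line. RNA of leukocytes in these cultures is argued against by 6 of their abundant transcripts (Ptprc, Tyrobp, Laptm5, Fcer1g, Coro1a and Lyz2), which changed by a median of -0.013 log2, and all 6 lay below log2 4 on every tolerant array. No biological explanation was tested, and time in culture stays open, since no unstimulated sample of that age is named.

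Splits of the arrays into 3 against 3 number 10 per comparison, the real one included, too few for a share under 0.05; the real split was the 1 with the highest count in each. It gave 6 genes at 6 h, 2470 in tolerant against unstimulated cells and 1238 in tolerant cells against 6 h, and the highest other split gave 0 each time. For lists the real values were 6, 12 and 7 and the highest others 3, 10 and 4, or 3, 10 and 3 among the 3 other splits that also part all 3 same-numbered pairs; the 6 others part 1 pair. Of 100 drawn splits of the 9 arrays into 3 groups, the real one included, 5 gave at least 3 genes still raised, so chance could not be excluded for that count over all splits. At least 6 genes lower than at 6 h came from 3 of the 100, and 692 genes changed late from 1 of the 100, shares under 0.05. The highest other values were 310, 300 and 625, so splits that mix the conditions can call many genes. The source of these calls was not tested. Of 100 drawn splits with 1 array of each replicate number in each group, the real one included, 3 gave at least 3 genes still raised. At least 6 lower than at 6 h came from 4 of them and at least 692 changed late from 1, and the highest other values were 256, 365 and 644. These splits were added after the first ones were seen, so their shares under 0.05 do not exclude chance.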

How the results depend on the processing

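The fit on replicates 2 and 3 only and the block of replicate 1 against the others were chosen after seeing the data. Of 156 named-gene calls none changed sign, but 25 were lost without tolerant replicate 2, 22 without tolerant replicate 3, 14 without unstimulated replicate 2 and 16 without the filter. The balance of higher and lower calls was not stable: in tolerant against unstimulated cells 53.4% of calls were higher, but 45.7% with quantile normalization (1097 higher and 1301 lower), 48.7% with array-median centring (1212 and 1275), 46.7% with the replicate block and 48.5% from replicates 2 and 3 only. Against 6 h the share was 54.1%, and 46.0% with centring (612 and 719). Counts not given here stayed within 1.5 times. The cause of the changes was not tested, except where fewer arrays, another unit or spread taken up by the replicate block set them.

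With the replicate block, genes at 6 h numbered 1092 higher, 1175 lower and 255 changed at least 2-fold, 2267 in all. For tolerant against unstimulated the blocked counts were 2142 and 2444 (4586 in all), and for tolerant against 6 h 1508 and 1477 (2985 in all). Still raised were 190, lower than at 6 h 29, and changed late 1094. The block ended none of the gene calls, and of the list calls only that of oxidative phosphorylation at 6 h (adjusted p = 0.0895). With the block of replicate 1 against the others, these were 1266, 1477 and 282 (2743 in all), 2223 and 2586 (4809), 1599 and 1593 (3192), 210, 30 and 1118. From replicates 2 and 3 only, 1859 genes fell in tolerant against unstimulated cells, 1055 rose and 1071 fell against 6 h (2126 in all), and 7 were still raised.

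Without the filter, 26 genes were higher and 11 lower at 6 h (37 in all), 10 by at least 2-fold, and 7 were still raised. With the mean of all probe sets these were 13, 1, 14, 11 and 7. Array-median centring left 5 still raised. Fitted on their own 6 arrays, 377 genes fell in tolerant cells against 6 h. With all probe sets as the unit, tolerant against unstimulated gave 2470 higher, 1749 lower (4219 in all) and 2545 by at least 2-fold, tolerant against 6 h 1034, 929 (1963) and 1279, with 5 still raised and 1154 changed late. With limma's treat at a 1.5-fold threshold, 477 and 253 genes passed in tolerant cells against unstimulated and 6 h. Lists shifted with an estimated correlation numbered 0, 0 and 1, and with fry 19 in tolerant against unstimulated cells and 16 against 6 h.

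Leaving out each array in turn, genes at 6 h ranged from 5 to 503 higher, 0 to 193 lower, 5 to 431 by at least 2-fold and 5 to 696 in all, with each highest value without 6 h LPS replicate 3. Tolerant against unstimulated ranged from 752 to 1474 higher, 648 to 1434 lower, 1034 to 1467 by at least 2-fold and 1400 to 2908 in all. Tolerant against 6 h ranged from 380 to 682 higher, 297 to 600 lower, 551 to 737 by at least 2-fold and 677 to 1282 in all. Still raised ranged from 3 to 297, lower than at 6 h from 4 to 53, and changed late from 459 to 709. Lists ranged from 4 to 7, 10 to 13 and 7 to 8. Genes near the array floor limit what can be seen, since 59.1% to 61.0% of probe sets lay below log2 4.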

Other observations

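No test in this part was chosen after the data were seen.

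Further lists, none with a camera call in this comparison, held members that changed in tolerant against unstimulated cells. Of all 9431 tested genes 26.2% were called there, so member counts near that share are not particular to a list. Ddit3, the gene of a transcription factor of the ER-stress response, rose 4.69-fold (its other probe set differed by -0.09 log2), while Chac1 fell 2.74-fold and Sdf2l1 2.55-fold (1 of 3 tolerant arrays below log2 4), with 3 of 21 measured ER-stress genes higher and 4 lower (3 and 4 when adjusted over the list alone, 5 and 9 with the replicate block; camera adjusted p = 0.53). Of 13 measured p53 and CDK-inhibitor genes 5 rose and 2 fell (5 and 3 when adjusted over the list alone, 5 and 4 with the replicate block; camera adjusted p = 0.19), with Btg2 up 4.39-fold, Gadd45b 4.29-fold and Gadd45a 2.25-fold. Cholesterol synthesis genes fell in 4 of 16 measured and rose in 1 (also when adjusted over the list alone, and 8 and 1 with the replicate block; camera adjusted p = 0.273), Mvk by 2.25-fold.

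Of 10 measured mesenchymal genes 3 rose and 1 fell in tolerant against unstimulated cells (also when adjusted over the list alone, and 3 and 2 with the replicate block; camera adjusted p = 0.332). Ccn2 rose 5.72-fold and Ccn1 3.11-fold, while the fibronectin gene Fn1 fell 1.94-fold. Stem-cell and Wnt genes rose in 2 of 7 measured and fell in 1 (also when adjusted over the list alone; camera adjusted p = 0.235), with Sox9 up 2.15-fold and Prom1 down 1.74-fold. Interferon-response genes rose in 3 of 15 and fell in 2 (also when adjusted over the list alone, and 5 and 2 with the replicate block; camera adjusted p = 0.344), Rsad2 by 2.31-fold and Oasl1 by 2.03-fold upward and Irf9 by 1.9-fold downward. Ptger4, a prostaglandin receptor gene, rose 3.78-fold, and Ptgds fell 2.38-fold.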
